A study of Homo sapiens with 58 samples.

How the data were processed

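Total RNA from human peripheral blood mononuclear cells was measured on 58 expression arrays, 1 array per sample. The labels divide the arrays into 6 groups: allergy patients before immunotherapy (8 arrays), allergy patients after immunotherapy (4), healthy controls (8), and 3 autoimmune groups labelled SLE (15), RA (8) and ERA (15). The labels do not expand ERA, and they give no batch. Label numbers of the groups before and after immunotherapy do not overlap, so these groups were compared as unpaired.

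The deposited values are intensities on a linear scale, given relative to a mean near 1. The scanner, the software and the scaling are not given in the sources used here. All values were above 0, between 0.01 and 126.91, and none was missing. The array means were exactly 1 (within 2e-04) in all control and RA arrays, in 12 of 15 SLE and 8 of 15 ERA arrays, and in none of the allergy arrays, where they ran from 0.818 to 0.985 before immunotherapy and from 0.861 to 0.964 after it. The arrays were thus not all on 1 scale as deposited.

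Of 4132 deposited probes, 4 for Y-linked genes or XIST were left out and 4128 were tested. The annotation gave 1 symbol for 1582 of the deposited probes, several symbols for 52 and none for 2498. The tested probes with 1 symbol numbered 1580 and covered 1530 symbols. The annotation gives no genome build, so no positions are reported. The assignment of symbols was checked on 65 pairs of probes with 1 symbol in common: their median correlation, after removal of group means, was 0.301, against -0.00405 for 10000 random pairs. The highest median among 10000 random lists of as many pairs was 0.124. The 95th percentile of random pairs was 0.398, so the check holds for the pairs as a set and not for each pair.

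Values were taken to log2 with a pseudocount of 0. The rule for scaling was fixed before the data were examined: if the array medians spanned more than 0.5 log2 units, quantile normalization would be the main setting. They spanned 2.1, from -2.47 to -0.377, and the log2 values were quantile-normalized. All levels are in log2 units on that scale.

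Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 58 arrays and 6 groups in a single model and so a spread shared by all groups. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 4128 probes of each comparison, with a threshold of 0.05. Errors printed as SE are limma standard errors. The 8 comparisons were fixed before the data were examined. Allergy before immunotherapy was also set against the unweighted mean of the 3 autoimmune groups. The fit was tested on simulated data with 100 probes raised or lowered by 2 log2 units per comparison, and recovered between 91% and 100% of them. Of 100 probes changed by 1 log2 unit it recovered 33% after against before immunotherapy, 37% after immunotherapy against controls, 55% before it against controls and 69% to 85% in the other comparisons. The simulated arrays had the same spread in every group. The real median SD of a probe was 0.657 before and 0.586 after immunotherapy, against 0.403 in controls, so recovery for the allergy groups may be lower. The number of arrays limits the precision: the median SE of a change was 0.342 with 4 against 8 arrays and 0.245 with 15 against 8.

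Genes were named by a rule fixed before the data were examined. Among probes that passed the threshold, had a single symbol and had a mean level above the 25th percentile in at least 1 of the groups compared, the 12 largest changes in each direction were taken for the 3 comparisons among allergy patients and controls, and the 6 largest in each direction for the others. To these were added up to 4 members of each gene list that passed its test and, for comparisons of the allergy groups, the 4 members of smallest p of the interferon-induced, Th1, Th2 and IgE effector, and regulatory T cell and tolerance lists. Other list members given as examples were chosen after their values were seen.

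Altogether 25 gene lists were fixed before the data were examined, and 11 had the 5 measured probes needed for a test. These were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and limma's fry beside it. List p-values were adjusted over the 11 lists of each comparison. Members of a list were also adjusted over the list alone. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

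To place the group after immunotherapy between the group before and the controls, the controls were divided at random into equal parts 20 times. Probes were called against 1 part and measured against the other. Concordance between diseases was measured across probes, beside 100 simulations of unchanged groups that share controls. After seeing the data, calls in both of 2 comparisons were also counted with different controls on each side, over the same 20 divisions taken both ways round. Array sets among the autoimmune arrays were found by average-linkage clustering of the correlations between arrays over the dimmer probes. Chance was tested with 100 divisions of the same arrays into groups of the same sizes, the real division included.

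Alternatives fixed before the data were examined were the values as deposited, arrays centred on their medians, a pseudocount of 0.25 (the 25th percentile of the values), probes above the median level only, a model of the compared groups only, no intensity trend, each array left out in turn, a block for label numbers in common, and the estimated correlation for the lists. Alternatives chosen after seeing the data were a spread of its own for each group, a block for array set, the array's 5th percentile as a covariate, arrays of mean exactly 1 only, and the fit without 2 allergy arrays that stood apart. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.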

Results

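Gene expression in peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes of blood, was measured in 58 samples. There were 8 arrays of allergy patients before immunotherapy, 4 of allergy patients after it, 8 of healthy controls, and 15, 8 and 15 of the autoimmune groups labelled SLE, RA and ERA. SLE and RA are the usual abbreviations of systemic lupus erythematosus and rheumatoid arthritis, and ERA is not expanded by the labels. Of the 4128 probes tested, 1580 had a single gene symbol.

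The median correlation across probes was 0.843 within the 8 control arrays and 0.608 between them and other arrays. Within the groups before and after immunotherapy it was 0.628 and 0.69, within SLE 0.739, within RA 0.859 and within ERA 0.862, and 2 of the 8 arrays before immunotherapy stood apart from all others. Clustering by measured values divided the 38 autoimmune arrays into 2 array sets: 13 arrays (7 RA and 6 SLE) and 25 arrays (15 ERA, 9 SLE and 1 RA). The deposited array median was 0.25 to 0.54 in controls, 0.31 to 0.77 before immunotherapy, 0.58 to 0.72 after it and 0.18 to 0.51 in the autoimmune groups. Probes were not independent replicates in these correlations.

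**Figure D1:**
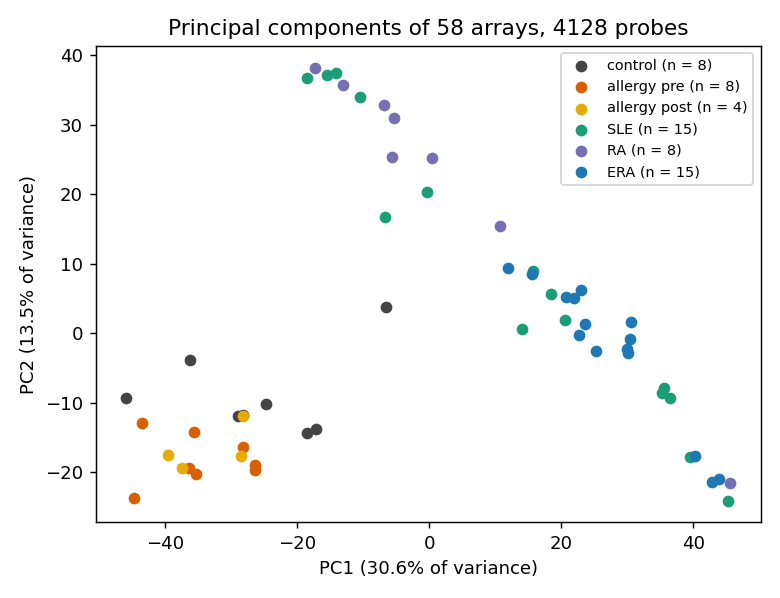
Principal components of the quantile-normalized log2 values, 1 point per array and 1 colour per group, with PC1 (30.6% of the variance) on the x axis and PC2 (13.5%) on the y axis. The 8 controls and the 12 allergy arrays overlapped in this plot and differed on PC3, which is not drawn. The 38 autoimmune arrays ran along an arc, without a gap between the array sets.

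Allergy patients before immunotherapy were first compared with healthy controls. CDKN1B, an inhibitor of cyclin-dependent kinases, was lower in patients, with a log2 change of -4.54 ± 0.38 (SE, n = 8 and 8, adjusted p = 7.2e-16), and lower in 8 of 8 patient arrays. MARCHF6, a ubiquitin ligase of the endoplasmic reticulum, changed by -4.50 ± 0.59, and EFNB1, a ligand of Eph receptors, by -4.08 ± 0.58. MAP3K5, a stress-activated kinase, changed by -3.35 ± 0.35 and STK38, a serine/threonine kinase, by -3.19 ± 0.34. DNASE1L1, a relative of DNase I, was higher by 3.57 ± 0.34 (adjusted p = 1.62e-13), without overlap between the groups. MRPL3, of the mitochondrial ribosome, was higher by 2.55 ± 0.27 at 1 of its 3 probes, and the others changed by 0.30 and -0.28 and did not pass.

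The other genes named as higher were MAN2A2, SRGN, EXT2, ESR1, MST1L, HTR3A, RPL31, ZNF148, KDM6A and PTP4A1, with changes of 2.04 to 2.68. SRGN, a proteoglycan of secretory granules, was 5.51-fold higher. The others named as lower were PWAR5, GNAO1, RGS4, MAPK10, BGN, ANKRD1 and SSX3, with changes of -3.63 to -3.06. GNAO1 is a G protein subunit, RGS4 a regulator of G protein signalling and MAPK10 a kinase of the JNK family.

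Of the 7 measured members of the T cell receptor signalling list, 1 rose, 4 fell and 2 did not pass, and the counts adjusted over the list alone were the same. The adaptors LCP2 and LAT changed by -2.08 ± 0.37 and -1.42 ± 0.25, and DGKZ, which removes diacylglycerol, by -1.49 ± 0.32. The GTPase RAC2 was the member that rose, by 1.09 ± 0.37. The list as a whole did not pass against other genes (camera, adjusted p = 0.144), but was lower and passed with the values as deposited (0.0171) and with centred medians (0.0254). Of 6 Th1 members, 3 rose (4 adjusted over the list alone) and none fell: STAT4, which transmits interleukin-12 signals, by 1.13 ± 0.22, IL15 by 1.01 ± 0.32 and IL15RA by 0.63 ± 0.20. The Th1 list did not pass either (adjusted p = 0.182). Without the 2 arrays that stood apart, IL15 and IL15RA no longer passed (adjusted p = 0.112 and 0.0687). IL18R1 had a change of 0.71 ± 0.30 and did not pass (adjusted p = 0.0593).

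STAT6, which transmits interleukin-4 signals, was the member of the Th2 and IgE effector list that changed, by -1.99 ± 0.38 (adjusted p = 3.23e-05). The other 2 measured members, CCL11 (0.20) and IL13RA2 (-0.19), did not pass, and a list of 3 probes was too small for a test. Of 9 members of the regulatory T cell and tolerance list, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. SOCS1, a suppressor of cytokine signalling, changed by -1.58 ± 0.28, SMAD3 by -1.05 ± 0.29 and SMAD4 by -1.13 ± 0.37. SMAD7 had a change of 0.69 and did not pass. SMAD4 no longer passed without the 2 arrays that stood apart (adjusted p = 0.0684), nor with the values as deposited (0.0516), and SMAD3 no longer passed in a model of these groups alone (0.0664). Of 15 interferon-induced members, PLSCR1 rose by 0.52 ± 0.15, while LY6E and BST2 changed by -1.03 ± 0.33 and -0.59 ± 0.20, and 12 did not pass. The list test gave an adjusted p of 0.764, and the 3 counts were the same adjusted over the list alone. With the values as deposited LY6E and BST2 no longer passed (0.0536 and 0.399), and RSAD2 had a change of -0.59 and did not pass.

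Markers of other blood cells moved beside these groups. Of 8 monocyte markers, CD163 and AIF1 rose by 0.99 ± 0.23 and 1.82 ± 0.42, LILRB2 changed by -2.51 ± 0.66 and 5 did not pass (list adjusted p = 0.688). Of 4 neutrophil and eosinophil markers, CEACAM1, CSF3R and CEACAM6 rose, by 1.23, 1.15 and 0.63. Of 12 immediate early genes, which also respond to the handling of blood, 3 rose and 4 fell, among them FOSL1 (-1.43 ± 0.22) and SGK1 (-1.72 ± 0.35), and the list adjusted p was 0.55.

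In all, 1267 of 4128 probes differed between patients before immunotherapy and controls, 644 higher and 623 lower. Of the called probes 50.8% were higher, against 67.7% with the values as deposited, in which the median change of all probes was 0.35. SRGN, MST1L and RPL31 did not pass with arrays centred on their medians (adjusted p = 0.087, 0.0722 and 0.121).

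**Figure D2:**
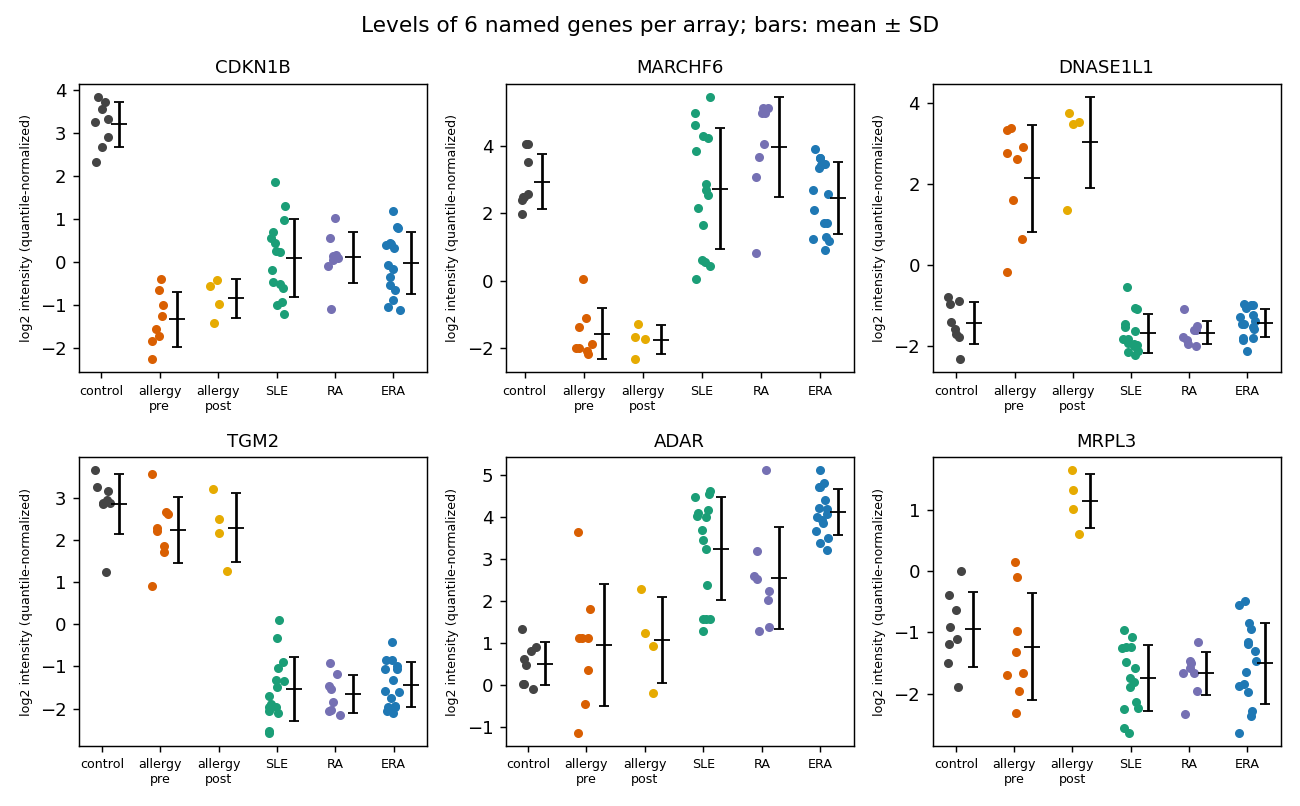
Quantile-normalized log2 intensity (y axis) of CDKN1B, MARCHF6, DNASE1L1, TGM2, ADAR and 1 probe of MRPL3 in each of the 6 groups (x axis). Each point is an array, and bars show the mean ± SD. The mean of CDKN1B was 3.20 in controls and -1.34 before immunotherapy, and that of TGM2 was 2.85 in controls and -1.65 in RA.

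Patients after immunotherapy were next compared with controls. DNASE1L1 was higher by 4.47 ± 0.42 (SE, n = 4 and 8, adjusted p = 1.16e-13) and MRPL3 by 3.38 ± 0.33 and 2.10 ± 0.37 at 2 of its 3 probes, the other changing by -0.60 without passing. MARCHF6 changed by -4.69 ± 0.73, EFNB1 by -4.15 ± 0.71, CDKN1B by -4.05 ± 0.46 and MAP3K5 by -3.71 ± 0.42, with no overlap between patient and control arrays for any of the 4. LILRB2, an inhibitory receptor of monocytes, changed by -3.56 ± 0.80. The other genes named as higher were EXT2, SEMA3F, RPL31, HTR3A, FMO5, MAN2A2, AIF1, POLR3C and TPD52 (1.78 to 2.46), and the others named as lower were GNAO1, PWAR5, STK38, MAPK10, BMP2, BGN and SSX3 (-3.48 to -2.65).

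STAT6 changed by -2.38 ± 0.46 and was the member of the Th2 and IgE effector list that passed; IL13RA2 (-0.57) and CCL11 (-0.05) did not. Of 9 regulatory T cell and tolerance members, SMAD3 and SOCS1 fell, with changes of -1.70 ± 0.35 and -1.52 ± 0.34, and 7 did not pass, among them TGFBR2 (1.33) and SMAD2 (0.67). With the values as deposited SMAD3 and SOCS1 no longer passed (adjusted p = 0.0693 and 0.161). Of 6 Th1 members, STAT4 rose by 0.76 ± 0.28 (adjusted p = 0.0377), and RUNX3 (-0.57), IL15 (0.48) and IRF1 (-0.20) were among the 5 that did not pass. In a model of these groups alone STAT4 did not pass (adjusted p = 0.058). None of the 15 interferon-induced members passed; CXCL10 (1.20), PLSCR1 (0.40), LY6E (-0.80) and BST2 (-0.42) had the smallest p. Of 16 apoptosis members 3 rose (4 adjusted over the list alone) and 2 fell: DAXX by 1.31 ± 0.28, BAK1 by 0.99 ± 0.30 and TNFRSF10B by 0.64 ± 0.23, with CASP4 (-1.84) and TRAF1 (-0.83, but 0.00 with the values as deposited) lower. The adjusted p of the regulatory, Th1, interferon and apoptosis lists was 0.82, 0.915, 0.82 and 0.82. Of 8 monocyte markers FCGRT rose by 1.30 ± 0.46 and AIF1 by 1.85 ± 0.51, LILRB2 was lower and 5 did not pass, and FCGRT and AIF1 did not pass with the values as deposited or with centred medians. None of the 4 neutrophil and eosinophil markers passed, but CEACAM6 was higher and passed with the values as deposited (adjusted p = 0.00189) and with centred medians (0.00807). Among 12 immediate early genes EGR3 and FOSL2 rose, by 0.85 and 1.13, and FOSL1 and SGK1 changed by -1.26 and -1.25 (2 higher and 3 lower adjusted over the list alone). With the values as deposited FOSL1 and FOSL2 did not pass, nor did EGR3 and FOSL2 with centred medians. The list adjusted p was 0.82 for both the monocyte markers and the immediate early genes.

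Of the 4128 probes, 873 differed between patients after immunotherapy and controls, 439 higher and 434 lower. Of these 50.3% were higher, against 85% with the values as deposited (median change of all probes 0.62) and 37.9% with centred medians. With centred medians SEMA3F, RPL31, MAN2A2, AIF1 and the weaker MRPL3 probe did not pass, and with a spread of its own for each group 557 probes were called.

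The group after immunotherapy was then compared with the group before it, which asks how expression differs with treatment. The label numbers of these groups do not overlap, and the labels do not say whether the same people gave both samples. At 1 of its 3 probes MRPL3 was higher after immunotherapy, by 2.39 ± 0.37 (SE, n = 4 and 8, adjusted p = 5.2e-05), and higher in 4 of 4 arrays. This was not the MRPL3 probe called before immunotherapy against controls. The other probes changed by 0.83 and -0.90 and did not pass. FOSL2, a subunit of the AP-1 transcription factor, was higher by 2.11 ± 0.35 and LAT, an adaptor of the T cell receptor, by 1.57 ± 0.30. CACNB3, a calcium channel subunit, changed by -2.21 ± 0.56 (adjusted p = 0.0183) and ATP1B3, a subunit of the sodium pump, by -2.14 ± 0.57. The others named as higher were ITIH4, NID1, LDHA (at 1 of 3 probes), ONECUT1, GBA2, ITPKC, TPD52, LST1 and PITPNM1 (1.53 to 2.02), and those named as lower were BRINP1, GNPAT, GRIA2 (at 1 of 3 probes), CRP, NAMPT, SLC19A1, CEACAM1, WWOX, EIPR1 and ID4 (-1.92 to -0.94).

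Both lists that passed in any comparison after quantile normalization did so here. Of 16 apoptosis members, DAXX and BAK1 rose by 1.27 ± 0.28 and 1.12 ± 0.30, and 14 did not pass (4 higher and 1 lower adjusted over the list alone). BAK1 promotes and DAXX modulates cell death. TNFRSF10B (0.65) and CASP10 (0.70) did not pass over all probes. The list was higher after immunotherapy against other genes (camera, adjusted p = 0.0203), with adjusted p = 0.0506 at an estimated correlation. The 6 Th1 members had a mean change of -0.55, and the list was lower (adjusted p = 0.0203, and 0.0485 at an estimated correlation). No Th1 member passed singly, either over all probes or adjusted over the list alone: IL18R1 had a change of -0.83, IL15RA -0.66, IL15 -0.53 and RUNX3 -0.52. Without the 2 arrays that stood apart the Th1 list did not pass (adjusted p = 0.0966), nor did it with the values as deposited (0.214) or with centred medians (0.0657). The apoptosis list did not pass with the values as deposited (0.0942) or with brighter probes alone (0.102). Without 1 of the 4 arrays after immunotherapy its adjusted p was 0.112, and without another it was 0.0798, as was that of the Th1 list. The Th1 list also missed the threshold without a further array of that group (0.0564) and without 1 of the 8 arrays before immunotherapy (0.0546).

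None of the Th2 and IgE effector members passed (STAT6 -0.40, IL13RA2 -0.38, CCL11 -0.25). In the regulatory T cell and tolerance list, SMAD4 (1.15), TGFBR2 (1.24), SMAD3 (-0.65) and SMAD2 (0.46) had the smallest p, and no member passed (list adjusted p = 0.967). In the interferon-induced list UBE2L6 (1.21), SP110 (0.75), TNFSF10 (0.58) and CXCL9 (0.31) had the smallest p, and no member passed (list adjusted p = 0.34). Of 7 T cell receptor signalling members LAT alone rose (2 adjusted over the list alone), with a list adjusted p of 0.122. None of the 8 monocyte markers passed. Of 4 neutrophil and eosinophil markers CEACAM1 was lower, at -1.24 ± 0.37 (adjusted p = 0.0479), and of 12 immediate early genes, which also respond to the handling of blood, FOSL2 was higher, with the same counts adjusted over the list alone (immediate early list adjusted p = 0.34). Neither gene passed with the values as deposited or with centred medians. The array 5th percentile of the deposited values averaged 0.412 after immunotherapy and 0.289 before.

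In all 119 of 4128 probes passed, 81 higher and 38 lower, and in 10 of 100 divisions of the 12 arrays at least as many did. No probe passed in limma with the values as deposited (median change of all probes 0.31), with centred medians or in a model of these groups alone (199, 183 and 280 had an unadjusted p under 0.05), 3 passed with a spread of its own for each group, and without 1 of the 4 arrays after immunotherapy 39 did.

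The probes that set patients before immunotherapy apart from 1 part of the controls were then measured after immunotherapy against the other part. Over 20 divisions of the controls a median of 827 probes was called. Their median change in the direction of the call was 1.19 before immunotherapy (0.945 to 1.35) and 0.912 after it (0.728 to 1.05). The sign was kept by 99.7% of them before and by 92.8% after immunotherapy. The value after immunotherapy depended on the processing. It was 0.593 with a pseudocount of 0.25 (0.791 before immunotherapy), 1.06 with centred medians (1.14 before), 1.27 with brighter probes (1.53 before) and 1.25 with the values as deposited, where it was not below the value before (1.22). Probes were chosen in the group before immunotherapy, which raises its value, and no test of the difference was made.

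SLE was compared with controls. GEMIN2, which takes part in the assembly of spliceosomal RNPs, changed by -4.42 ± 0.34 (SE, n = 15 and 8, adjusted p = 1.19e-17), and TGM2, a transglutaminase, by -4.39 ± 0.31. Both were lower in 15 of 15 SLE arrays. BRCA1, of DNA repair, changed by -3.89 ± 0.37, and MAN1A1, AP3S2 and GUCY1B1 by -3.60 to -3.57. ADAR, an RNA-editing enzyme induced by interferon, was higher by 2.73 ± 0.43, and NCAM2, USP6NL, EGFR, APBB2 and HSD11B2 were higher by 2.38 to 2.57. The rise of ADAR was not uniform. Its level was 1.282 to 3.247 in the SLE arrays of the smaller array set and 3.458 to 4.615 in those of the larger. The sets were themselves found from measured values.

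Of 15 interferon-induced members 3 rose, ADAR, IRF1 (1.49 ± 0.23) and PLSCR1 (0.41 ± 0.13), BST2 fell, with a change of -0.78 ± 0.18, and 11 did not pass, with the same counts adjusted over the list alone. The list did not pass against other genes (adjusted p = 0.617). Of 6 Th1 members IRF1 and IL15 (1.31 ± 0.28) rose, 3 adjusted over the list alone (list adjusted p = 0.309). In the regulatory T cell and tolerance list TGFBR2, SMAD4 and ENTPD1 rose by 1.30, 0.84 and 0.46, and SOCS1 and SMAD3 changed by -1.73 and -1.63 (list adjusted p = 0.849). Of 12 immediate early genes 4 rose and 3 fell (6 and 3 adjusted over the list alone), with JUNB (1.64 ± 0.29) and SGK1 (1.75 ± 0.30) higher and FOSL1 (-1.47 ± 0.19) lower (list adjusted p = 0.64). Beside these, 3 of 8 monocyte markers rose and 1 fell (MNDA 1.75, FCN1 -0.83), and CSF3R, a neutrophil marker, rose by 2.18 ± 0.38.

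Between SLE and controls 1561 probes differed, 805 higher and 756 lower. Of these 51.6% were higher, against 20.8% with the values as deposited, in which the median change of all probes was -0.33.

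RA was compared with controls in the same way. TGM2 changed by -4.50 ± 0.35 (SE, n = 8 and 8, adjusted p = 4.56e-17), GNB5, a G protein subunit, by -4.05 ± 0.44, GEMIN2 by -3.92 ± 0.39 and BRCA1 by -3.88 ± 0.42, each lower in 8 of 8 RA arrays. MAN1A1 and AP3S2 changed by -3.67 and -3.51. SRGN was higher by 2.50 ± 0.57, in 7 of 8 arrays, and JUNB, an AP-1 subunit, by 2.04 ± 0.33, in 8 of 8. NCAM2, PPIC, GPER1 and APBB2 were higher by 2.04 to 2.19.

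Of the 15 interferon-induced members 5 rose and 1 fell (5 and 2 adjusted over the list alone), with ADAR higher by 2.03 ± 0.49, IRF1 by 1.43 ± 0.27 and TRIM22 by 1.10 ± 0.42 (list adjusted p = 0.432). Of 6 Th1 members 3 rose (4 adjusted over the list alone): IRF1, IL15 by 0.87 ± 0.32 and STAT4 by 0.80 ± 0.22 (list adjusted p = 0.183). STAT6 changed by -1.12 ± 0.38. Of 12 immediate early genes 5 rose and 3 fell, the same adjusted over the list alone, with SGK1 higher by 1.57 and FOSL1 lower, at -1.54 (list adjusted p = 0.432). Among the markers, CSF1R, MNDA and AIF1 of 8 monocyte markers rose, by 1.34, 1.22 and 1.94, and none fell (list adjusted p = 0.237). Of 4 neutrophil and eosinophil markers CSF3R and CEACAM6 rose, by 1.21 ± 0.43 and 0.56 ± 0.19. With the values as deposited neither passed, and CSF3R did not with centred medians.

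Between RA and controls 1273 probes differed, 595 higher and 678 lower. The share of higher probes was 46.7%, against 24.9% with the values as deposited.

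ERA was compared with controls. GEMIN2 changed by -4.68 ± 0.34 (SE, n = 15 and 8, adjusted p = 7.54e-19), TGM2 by -4.29 ± 0.31 and BRCA1 by -4.14 ± 0.37. HSD11B2, which inactivates cortisol, was higher by 3.66 ± 0.51, ADAR by 3.60 ± 0.43, and CSF3R, the receptor for granulocyte colony-stimulating factor, by 3.49 ± 0.38. UNC13B, USP6NL and MLX were higher by 3.56 to 3.57, and GUCY1B1, AP3S2 and MAN1A1 changed by -4.11 to -3.63. All 12 of these probes separated the 15 ERA arrays from the controls without overlap.

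Of 15 interferon-induced members 4 rose and 1 fell, of 6 Th1 members 4 rose and none fell, and of 9 regulatory T cell and tolerance members 4 rose and 3 fell, each count the same adjusted over the list alone. IL15 and IL18R1 rose by 1.39 ± 0.28 and 1.12 ± 0.26, TGFBR2 by 2.41 ± 0.46, and SOCS1 changed by -2.07 ± 0.25. These lists did not pass against other genes (adjusted p = 0.852, 0.22 and 0.906). Of 7 T cell receptor signalling members PIK3CD rose by 1.25 and LAT, FYB1 and DGKZ changed by -1.40, -1.45 and -0.99 (list adjusted p = 0.852). Of 8 monocyte markers 3 rose and 2 fell (MNDA 2.73, LILRB2 -1.94), and all 4 neutrophil and eosinophil markers rose, CSF3R the most, of which CSF3R alone passed with the values as deposited. Among the 12 immediate early genes 4 rose and 3 fell (4 and 4 adjusted over the list alone), with SGK1 (1.83 ± 0.30), JUNB (0.99), RGS1 (0.85) and IER2 (0.56) higher and FOSL2 (-1.48), FOSL1 (-1.29) and JUN (-1.03) lower (list adjusted p = 0.906). RGS1 and IER2 did not pass with the values as deposited.

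Between ERA and controls 1824 probes differed, 927 higher and 897 lower. The share of higher probes was 50.8%, against 25.7% with the values as deposited, in which the median change of all probes was -0.40.

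**Figure D3:**
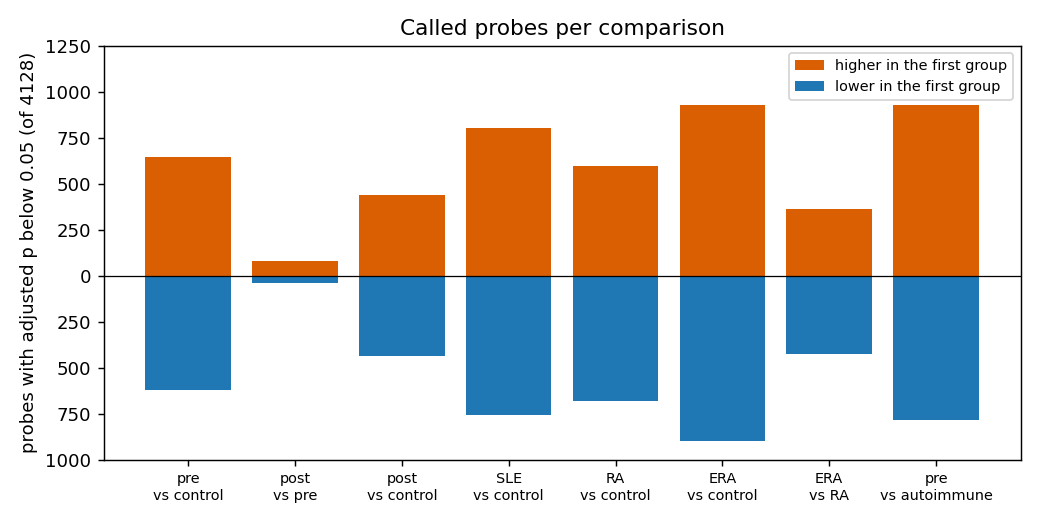
Number of probes with an adjusted p under 0.05 in each comparison (y axis, of 4128 probes), with probes higher in the first-named group above 0 and lower ones below. The counts ran from 119 after against before immunotherapy to 1824 in ERA against controls.

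The autoimmune groups labelled ERA and RA were compared directly. CSF3R was higher in ERA by 2.29 ± 0.38 (SE, n = 15 and 8, adjusted p = 0.000143), HSD11B2 by 2.26 ± 0.51 and TGFBR2, a receptor for TGF-beta, by 2.18 ± 0.46. SSX3 changed by -2.23 ± 0.50, PWAR5 by -2.03 ± 0.48 and ATXN2L by -1.90 ± 0.41. KLK6, UNC13B and TMEM187 were higher by 1.94 to 2.14, and BGN and both probes of ACTB, the cytoskeletal actin, changed by -1.79 to -1.77. The ACTB probes did not pass with the values as deposited (adjusted p = 0.0634 and 0.0668) or with centred medians (0.116 and 0.117).

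Of 8 monocyte markers 4 were lower in ERA and 1 higher, the same adjusted over the list alone: LILRB2 (-1.71 ± 0.57), TYROBP (-1.42 ± 0.49), AIF1 (-1.18 ± 0.37) and FCN1 (-1.12 ± 0.30) against MNDA (1.51 ± 0.33). The list adjusted p was 0.363. Of 12 immediate early genes JUNB and KLF4 were lower, at -1.05 and -0.90 (list adjusted p = 0.363). STAT6 was higher by 1.21 ± 0.33. In the interferon-induced list ADAR was higher by 1.57 ± 0.43, TRIM22 and UBE2L6 were lower, at -1.41 ± 0.37 and -0.84 ± 0.31, and the other members did not pass. All 15 ERA arrays lay in the larger array set and 7 of 8 RA arrays in the smaller. When the 15 SLE arrays were clustered alone over the dimmer probes, into 10 and 5 arrays, the difference between these clusters correlated with the ERA and RA difference at 0.906 over the brighter probes, where 100 random divisions of the SLE arrays gave at most 0.876 (sign ignored, median 0.525).

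Between ERA and RA 788 probes differed, 365 higher and 423 lower; the share of higher probes was 46.3%, against 63.4% with centred medians, and the median change of all probes was -0.28 with the values as deposited. Without 1 RA array at a time the count ran from 457 to 1188. The highest count was without the only RA array in the larger array set. With array set as a block 10 of the 12 probes named first changed direction, among them HSD11B2 (-0.26), TGFBR2 (-0.17), SSX3 (0.68) and PWAR5 (0.61), CSF3R and ATXN2L did not pass, and 1 probe passed in all (limma, 340 with an unadjusted p under 0.05). The sets were found from these same arrays and nearly coincide with the diagnoses, so that fit rests on 1 RA array and decides nothing about the difference.

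Allergy before immunotherapy was compared with the mean of the 3 autoimmune groups, which asks how allergy and autoimmune disease differ. A difference can arise on either side. BRCA1 was higher in allergy by 4.07 ± 0.33 (SE, n = 8 and 38, adjusted p = 1.01e-16), TGM2 by 3.76 ± 0.28 and DNASE1L1 by 3.74 ± 0.27, each in 8 of 8 allergy arrays, and MAN1A1 was 16-fold higher. MARCHF6 changed by -4.62 ± 0.47, GPER1, a membrane receptor for estrogen, by -3.72 ± 0.28, and SGK1, a kinase induced by glucocorticoids, by -3.43 ± 0.27. AP3S2 and GEMIN2 were higher by 3.69 and 3.49, and MAP3K5, STK38 and USP6NL changed by -3.42 to -3.36. Mean levels before immunotherapy and in controls were 3.995 and 3.895 for BRCA1, 2.223 and 2.851 for TGM2, and 2.869 and 3.719 for GEMIN2. In the autoimmune groups they averaged -0.075, -1.541 and -0.619, so these differences lay mostly on the autoimmune side. DNASE1L1 differed on the allergy side, at 2.14 before immunotherapy, -1.434 in controls and -1.599 in the autoimmune groups.

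Of 15 interferon-induced members 5 were lower in allergy and none higher, the same adjusted over the list alone, with ADAR at -2.36 ± 0.38, IRF1 at -1.13 ± 0.21, UBE2L6 at -1.02 ± 0.27 and SP110 at -0.72 ± 0.23. Before immunotherapy against controls these genes changed by 0.43, 0.19, -0.71 and -0.25, and none passed. The list did not pass against other genes (adjusted p = 0.22, and 0.42 at an estimated correlation). With the values as deposited SP110 had a change of 0.16 and UBE2L6 did not pass (adjusted p = 0.434). STAT6 changed by -1.47 ± 0.30, with CCL11 (0.25) and IL13RA2 (-0.17) not passing. Of 6 Th1 members IL15RA and STAT4 were higher by 0.62 and 0.53, IRF1 was lower, and RUNX3 (-0.39) did not pass (list adjusted p = 0.934). In the regulatory T cell and tolerance list SMAD4 changed by -2.07 ± 0.29 and TGFBR2 by -1.22 ± 0.41, SMAD3 was higher by 0.59 ± 0.22, and SOCS3 (0.44) did not pass (list adjusted p = 0.934). Without the 2 arrays that stood apart TGFBR2 and SP110 did not pass (adjusted p = 0.0562 and 0.0517), nor did SMAD3 with centred medians (0.0535). Of 8 monocyte markers 3 were higher and 3 lower, among them FCGRT (0.74) and MNDA (-1.97), and FCN1 was higher by 0.72 but lower with centred medians (-0.81, adjusted p = 0.0169). Of 4 neutrophil and eosinophil markers CEACAM1 was higher (0.74) and CSF3R and ALPL lower (-1.14 and -0.85). In the immediate early list of 12 genes EGR3 was higher (0.51) and SGK1, JUNB (-2.05) and KLF6 (-1.03) lower, the same adjusted over the list alone (list adjusted p = 0.22). ALPL and KLF6 did not pass with the values as deposited, nor did CEACAM1 with centred medians.

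In this comparison 1714 probes differed, 928 higher in allergy and 786 lower. The share of higher probes was 54.1%, against 85.2% of 2830 with the values as deposited (median change of all probes 0.73) and 42.8% with centred medians; with a spread of its own for each group 1122 were called.

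Tested with fry, which does not compare a list with other genes, the Th1 members were higher on balance than in controls before immunotherapy (adjusted p = 4.89e-07) and in SLE (9.48e-09), RA (3.1e-08) and ERA (3.93e-10). After against before immunotherapy fry gave 0.000185 for the Th1 list and 0.000925 for the apoptosis list. In the regulatory T cell and tolerance list the median and mean change differed in sign against controls before immunotherapy (0.14 and -0.22), after it (0.09 and -0.09), in SLE (0.30 and -0.04) and in RA (0.23 and -0.16), as well as after against before immunotherapy (-0.05 and 0.13) and in allergy against the autoimmune groups (0.16 and -0.18). In ERA both were above 0 (0.05 and 0.07) while the list test pointed down. Median and mean also differed in sign for the Th1 list after immunotherapy against controls (median -0.08, mean 0.05), the interferon-induced list in ERA (-0.05 and 0.28) and the monocyte markers in allergy against the autoimmune groups (0.41 and -0.18).

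The changes of allergy and autoimmune groups against controls were then set side by side. CDKN1B was lower in all 5 patient groups, with a mean change of -3.60, as were HNRNPUL1 (-2.66), HGS (-2.60) and CCR6 (-2.30), a chemokine receptor. MAN2A2 was higher in all 5, with a mean change of 1.77, and so were ADD3 (1.09) and the transcription factor RUNX1 (0.85). These genes were chosen after their values were seen, by the size of their mean change or, for CCR6 and RUNX1, by their known function. Altogether 233 probes were called in 1 direction in all 5 comparisons, 35 higher and 198 lower, and 87 of them had a single symbol. All 5 comparisons used the same 8 control arrays.

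Of the 623 probes lower before immunotherapy, 373 were also lower in SLE and 34 were higher; of the 644 higher ones, 220 were also higher in SLE and 23 were lower. Since controls in common raise such overlaps, the calls were also made with different controls on each side. Both sides were parts of the same 8 control arrays. This removes shared sampling error but not a departure common to all controls. Over the dimmer probes the control arrays correlated at 0.612 with each other and 0.0649 with other groups. In RA these values were 0.408 and 0.127, and in ERA 0.394 and 0.0887. A departure common to all controls could by itself give the overlaps and correlations below. Over the 6 pairs of an allergy and an autoimmune group, the probes lower in both were then a median of 3.42 to 4.15 times as many as independent calls would give, and the probes higher in both 0.942 (after immunotherapy and ERA) to 2.41 times (before immunotherapy and RA). Across probes the changes before and after immunotherapy correlated at 0.798, and at a median of 0.732 with different controls on each side. The 6 pairs of an allergy and an autoimmune group correlated at 0.341 to 0.454 and the 3 pairs of autoimmune groups at 0.787 to 0.937. Unchanged groups that share controls gave a simulated mean of 0.344 to 0.555 for the 6 pairs. Only after immunotherapy with RA was the real value above its own simulated mean (0.428 against 0.344). Before with after immunotherapy (0.798) and RA with ERA (0.787) lay under their highest simulated values (0.83 and 0.873). SLE exceeded its highest with RA (0.916 against 0.825) and with ERA (0.937 against 0.912). The simulated groups held no change, so shared controls made up much of their variance. Their correlations therefore cannot be set against the real ones to judge concordance. The real covariance of the 6 pairs was 0.294 to 0.344, against simulated means of 0.0439 to 0.0541. A departure common to all controls would raise the real covariance too. With different controls on each side the 6 pairs kept median correlations of 0.298 to 0.386.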

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

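The tests of spread, normalization, array scaling, array batch, array set and monocyte share below were chosen after related results had been seen; the divisions of the arrays were planned before.

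Differences between patient groups were the first to stand out. After against before immunotherapy 119 probes differed, between ERA and RA 788, and between allergy before immunotherapy and the autoimmune groups 1714. Among 195 combinations of a group and a measure, 21 had a single array far from the others. The gap between that array and its nearest neighbour is given as a share of the group's range. Only the allergy, control and RA groups were tested in this way, so nothing is known here of single SLE or ERA arrays. By chance a single test gives a far array about 1 time in 20. The tests were not independent, because 1 array can be far from the others for several genes. The 21 therefore cannot be judged against that share. The median of 1 control array was low (0.544), as was TGM2 in 1 control array (0.671). Before immunotherapy 1 array was low for SRGN (0.576), RPL31 (0.764), MAN1A1 (0.683) and GEMIN2 (0.532), and 1 was high for LAT (0.542), PITPNM1 (0.594), CEACAM1 (0.542) and EIPR1 (0.557). After immunotherapy 1 array was low for GNPAT (0.842) and DNASE1L1 (0.885). In RA 1 array was low for SRGN (0.529), SSX3 (0.656), PWAR5 (0.69), BGN (0.609), MARCHF6 (0.526) and both ACTB probes (0.668 and 0.704), and 1 was high for CSF3R (0.556) and KLK6 (0.551). For MARCHF6 the low array was the only RA array in the larger array set.

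The 119 probes that differed after immunotherapy lay in groups whose arrays varied more than the others: the median SD of a probe was 0.657 before and 0.586 after immunotherapy, against 0.403 in controls. With a spread of its own for each group 3 probes passed. Simulated groups without change, in which each probe kept its measured SD in each group, gave 36 to 86 calls. Those SDs came from as few as 4 arrays, and their error entered as real inequality, so these calls may be too many. Unequal spread under a shared estimate is a candidate explanation, for a share of the count that the simulation does not fix. With arrays centred on their medians the called probes kept a median of 0.603 of their change, with a median size of 0.722 against 1.27 and an SE of 0.309 against 0.322, so calls ended because changes shrank; a part made by quantile normalization cannot be told apart from a real one, since the value lies between the bounds set for either. In 10 of 100 divisions of the 12 arrays as many probes passed, the highest other count being 271, which points to structure among these arrays, and chance is not excluded. An effect of immunotherapy stays open too, since the groups share 0 label numbers and treatment cannot be told apart from a difference between people.

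The control arrays were closer to each other (0.843 over all probes) than to other arrays (0.608). Correlation with arrays outside the group was lower before and after immunotherapy (0.529 and 0.562) and higher in the autoimmune groups (0.657 to 0.678). Quantile normalization removes any factor that scales a whole array, so such a factor cannot give the 1273 calls between RA and controls. That the arrays of both groups have a mean of exactly 1 therefore adds nothing to this count. With the values as deposited, where a factor would remain, 868 probes passed between RA and controls. Scaling by a single factor per array is thus argued against as the whole cause, and other forms of scaling were not tested. Over the dimmer probes control arrays correlated with each other at 0.612 and with other groups at 0.0649. RA (0.408 and 0.127) and ERA (0.394 and 0.0887) had such a pattern too, less strongly. The pattern in controls would go with an array batch, but all control arrays are of 1 group, so a batch cannot be told apart from health. Disease stays open on the same ground: 233 probes were called in 1 direction in all 5 comparisons with the same controls. The comparisons with controls exceeded other divisions of the same arrays, which argues against chance within the limit of 100 divisions. The real count was reached by 1 of 100 divisions, the real one, in each case (before immunotherapy 1267 against a highest other of 535, after it 873 against 276, SLE 1561 against 844, RA 1273 against 487, ERA 1824 against 765). These divisions do not tell a batch from disease.

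Clustering by measured values divided the autoimmune arrays into 2 array sets, which dimmer and brighter probes placed alike for 37 of 38 arrays, although no gap parted them on the first principal components. Diagnosis does not account for them alone, since 6 SLE arrays lay in the smaller set and 9 in the larger. Monocyte share stays open as a cause. Within SLE 5 of 8 monocyte markers passed as lower in the larger set (LILRB2 -2.67, TYROBP -2.42). CSF1R (-0.77) and CD163 (-0.55) were lower without passing, and MNDA alone was higher, by 1.54 ± 0.29. The rule set for this test reads calls in both directions as evidence against monocyte share as the whole cause, but 1 marker met it. The sets were also found from these same arrays, so calls between them are not independent of the clustering. An array batch behind the ERA and RA difference cannot be told apart from diagnosis, because 1 RA array and no ERA array broke the pattern. A fit with array set as a block (1 probe between ERA and RA) decides nothing here, since the sets were found from the same arrays and the fit rests on that RA array. The clusters of the SLE arrays alone, found over dimmer probes, differed over brighter probes much as ERA and RA did (correlation 0.906, at most 0.876 in 100 random divisions of the SLE arrays). Part of the ERA and RA pattern is thus also present within SLE, which does not tell a batch from a difference between patients. Chance is argued against for ERA against RA (788 against a highest other of 252) and for allergy against the autoimmune groups (1714 against 14). In both 1 of 100 divisions was as large, the real one, which is the smallest share these divisions can give.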

How the results depend on the processing

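The fits with a spread of its own for each group, array set as a block, the array's 5th percentile as a covariate, arrays of mean exactly 1 and without the 2 arrays that stood apart, and all alternatives of the position after immunotherapy and of concordance, were chosen after seeing the data. Fits of single array sets were also run and left out, because they chose samples by measured values and partly rested on 1 array. Where a cause is not given, the cause was not tested.

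Counts stayed within 1.5 times their value in the settings not listed here. With centred medians the median change of all probes was 0.16 in SLE and RA and 0.13 in ERA. With brighter probes alone, fewer probes were tested: before immunotherapy against controls 678 passed, after it against controls 458, after against before 42, SLE 910, RA 765 and ERA 1065. After against before immunotherapy, limma called 0 with the values as deposited, 0 with centred medians and 0 in a model of these groups alone (unadjusted p under 0.05: 199, 183 and 280), 3 with a spread of its own for each group and 211 with the 5th percentile as a covariate. A spread of its own for each group gave 557 after immunotherapy against controls, 1191 for ERA against RA and 1122 for allergy against autoimmune; a model of the compared groups alone gave 1265 for ERA against RA, and the values as deposited 2830 for allergy against autoimmune.

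With label number as a replicate block, over the numbers in common, 29 probes passed after immunotherapy against controls, 731 in SLE and 1620 in ERA, with fewer arrays. Residuals of arrays with the same number had mean correlations of -0.0096, -0.042 and -0.082, against 0.037, 0.024 and 0.0089 for other pairs, so the numbers were not read as pairing. With array set as a block, a fit that rests on 1 RA array and on sets found from the same arrays and so says nothing about stability, 1 probe passed between ERA and RA, and these changes turned: HSD11B2 -0.26, TGFBR2 -0.17, KLK6 -0.37, UNC13B -0.21, TMEM187 -0.08, SSX3 0.68, PWAR5 0.61, ACTB 1.65 and 1.54, and BGN 0.67. SP110 turned to 0.16 in allergy against autoimmune with the values as deposited. No other gene named by the rule turned in these settings. Of 292 calls of list members over all comparisons, 7 turned or came to 0 and 100 no longer passed with the values as deposited, and 2 turned and 57 no longer passed with centred medians. Single genes were not followed with arrays left out.

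Over all comparisons 2 gene lists passed, Th1 and apoptosis after against before immunotherapy. With the values as deposited 1 passed, the T cell receptor signalling list before immunotherapy against controls. With centred medians 2 passed, that list and apoptosis after against before. With an estimated correlation 1 passed (Th1), without the 2 arrays that stood apart 1 (apoptosis), and with brighter probes alone 0, where fewer probes were tested and the Th1 list was too small. The median change after immunotherapy of probes called before it was 1.25 with the values as deposited, 1.06 with centred medians, 0.593 with a pseudocount of 0.25 and 1.27 with brighter probes, and mean concordance was 0.347 to 0.402.

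Leaving out 1 array at a time gave 1143 to 1307 before immunotherapy against controls, 702 to 954 after it, 39 to 181 after against before, 1384 to 1576 in SLE, 1113 to 1293 in RA, 1695 to 1838 in ERA, 457 to 1188 for ERA against RA and 1594 to 1730 for allergy against autoimmune. After against before, 39 was without 1 of the 4 arrays after and 181 without 1 of the 8 before; for ERA against RA 4 single RA arrays moved the count, to 457, 474, 523 and 1188. Adjusted p ran from 0.00334 to 0.112 for the apoptosis list and from 0.0126 to 0.0798 for the Th1 list. Signal over background limits the dimmer probes: the array 5th percentile ran from 0.05 to 0.51 and the array median from 0.18 to 0.77.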

Other observations

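Values in this part are of lists fixed before the data were examined, with members chosen as examples after their values were seen. IRF4, a transcription factor of lymphocytes and dendritic cells, was lower than in controls in SLE (-2.30 ± 0.28), RA (-2.60 ± 0.32) and ERA (-2.62 ± 0.28), and after immunotherapy (-1.10 ± 0.40). In RFXAP, a regulator of MHC class II genes, the change was -0.80, -0.66 and -1.06 in SLE, RA and ERA and -0.56 before immunotherapy (adjusted p = 0.0445, but 0.625 with the values as deposited and 0.0791 with centred medians), and it did not pass after it (-0.25), and in TAPBP, which loads MHC class I, -1.20, -0.95 and -1.55 in the autoimmune groups and -0.96 after immunotherapy, where it did not pass. Other members of these 2 lists went the other way. LGMN of the class II list changed by 0.39 in SLE and 0.37 in RA, and PSMA1 of the class I list by 0.83 and 0.89, without passing. In ERA against RA both had changes above 0 (0.31 and 0.77) that did not pass either. PSME3 of the class I list rose in RA (0.82) and was lower in ERA than in RA (-1.26 ± 0.27). CD79B, a subunit of the B cell receptor, was higher in SLE (0.86 ± 0.25) and ERA (1.08 ± 0.25), and KIF11, a mitotic motor, was higher in both (1.43 ± 0.51 and 2.55 ± 0.51). DNAJB1, a chaperone, was lower in all 5 patient groups, with changes of -2.45 and -1.45 before and after immunotherapy and -1.17, -0.94 and -1.37 in SLE, RA and ERA.

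Before immunotherapy against controls, 3 of 13 cell cycle members rose and 1 fell (list adjusted p = 0.688), with CHEK1 (1.26), CDC6 (0.66) and BUB1B (0.51) higher and POLE (-0.75) lower. Of 9 MHC class I and proteasome probes TAPBP fell, with a change of -1.19 (list adjusted p = 0.795). Of 9 heat shock and chaperone probes 1 rose and 1 fell, CCT3 and DNAJB1 (median 0.03, mean -0.14, list adjusted p = 0.862). The other probe of CCT3 changed by 0.14 and did not pass. Of 5 oxidative phosphorylation probes CYCS rose by 1.48 and SDHD fell, with a change of -1.26 (median -0.05, mean 0.03, list adjusted p = 0.917). Of 16 apoptosis members CYCS and TRAF6 (0.66) rose and CASP4 (-1.89) and BAD (-0.70) fell (list adjusted p = 0.688).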
